A study of Mus musculus with 9 samples.

How the data were processed

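Per the labels, neutrophils were sorted on a FACS Aria III, RNA was extracted with a TRIzol-type reagent, and polyA libraries were made with a TruSeq mRNA kit, which the labels name as both a standard and a stranded kit. The markers and gates of the sort, and how the tissues were dispersed, are not given in the sources used here. The submitters' notes name Bowtie2, STAR, StringTie 2.1.3b, RSEM and DESeq2 and the build mm10. The roles and order of these tools, and the other versions, are not given in the sources used here.

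The deposited series table holds, per the file headers, an estimated read count and an FPKM for each of 36780 RefSeq transcripts in 9 libraries. The counts were whole numbers and not normalized, although the table's name says so: within each library the FPKM equalled the count divided by transcript length and by 1 constant. They were summed by Entrez gene to 24532 genes, and positions are the outermost transcript ends listed in mm10. The deposited files of the bone marrow libraries repeat the series table in all 36780 transcripts. Those of the blood and lung libraries hold RSEM expected counts and TPM for 55450 GENCODE genes, per the file headers, and the series table held about 2.00 to 2.02 times these expected counts. The plan, written before the data were examined, assumed RSEM expected counts for all libraries. The series table was used instead, because it alone covers the 3 tissues in 1 annotation. Mitochondrially encoded genes, immunoglobulin constant genes, Trac and Trbc2 are absent from it. The deposited column numbers run 1 above the replicate numbers of the titles, and the titles' numbers are used here.

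Genes were kept by edgeR's filterByExpr, which left 13510 genes. Counts of all 9 libraries were scaled by the trimmed mean of M-values and fitted with edgeR 4.0.16, robust quasi-likelihood and group means. Contrasts were tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.448. A gene was highest in a tissue when it passed and was higher in both contrasts. SE is the absolute log2 fold change divided by the square root of F. Limma 3.58.1, DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used. DESeq2 gave no adjusted p for 14 genes in each comparison.

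A set of 35 gene lists was fixed before the data were examined, and 33 had at least 5 tested genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation and with fry. Mitochondrially encoded genes were tested only in lung against blood, with edgeR on RSEM counts, and the 4 tested sex-linked genes were too few for a list test. For DESeq2, limma-voom, FPKM and 6-library alternatives the list test was run on signed z values.

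Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls per comparison among genes with adjusted p under 0.05, at least 20 CPM in the higher tissue and no overlap of replicates, without predicted genes, plus 10 genes followed in every comparison, 1 of which is not reported here, nor is 1 list example. From each list the rule takes 2 to 4 of the largest passing members with at least 5 CPM. The text prints fewer than that for many lists, a choice made after the values were seen. The other list examples first drawn up all stayed in the alternatives. Leaving out 1 library changed the call of 3 of 27 in blood against bone marrow, 5 of 38 in lung against blood and 4 of 22 in lung against bone marrow, and none of these (Gapdh, H2-Aa, H2-Ab1, Ccl22, Il1r2, Myc, Sftpd, Tnfaip6, Dcn, Marco, Rpl14 and Tek) is described as changed in the results, so the examples printed are steadier than the rule's full set. Col3a1, Cd79a and Ddx3y were named after their values were seen.

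Titles share replicate numbers across tissues. Deviations from tissue means correlated at 0.106 to 0.560 in all 9 same-numbered pairs, all over 0.1, against -0.593 to 0.504 in the other 18 pairs, and 13 of 18 best matches were to the own number. By the rule used here the numbers therefore pair the samples, as a hint from the data, since the labels name no shared animal or day. The hint was clearest for replicate 3 (0.508 marrow to blood, 0.514 blood to lung, 0.243 marrow to lung). Bone marrow replicate 1 matched blood replicate 2 (0.504) better than blood replicate 1 (0.208), as did lung replicate 1 (0.491 and 0.106). Replicate 3 was lowest in summed B-cell, T and NK cell and erythroid transcripts in every tissue, so its matches need not mean shared animals.

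A self-test planted 200 changed genes among 13510 in simulated counts with the spread of these libraries. EdgeR called 21.4%, 28.9% and 38.2% of genes in the real comparisons. With fewer changed genes the Benjamini-Hochberg cutoff is stricter, so the recovery may understate that in the real data. At an 8-fold change edgeR recovered 64%, 54% and 66% of 50 genes in the 3 comparisons, and at a 2-fold change 10%, 4% and 18%. False calls were 1.56%, 3.39% and 10.5% of calls. The limit of 10% was first set per comparison and was applied to the pooled calls after lung against bone marrow had exceeded it.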

Results

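Neutrophils, the short-lived granulocytes of the innate immune system, were sorted by fluorescence-activated cell sorting from the bone marrow, blood and lung of wild-type C57BL/6 mice. Polyadenylated RNA of the sorted cells was sequenced. Each tissue had 3 biological replicates, giving 9 libraries. The design asks how neutrophils differ between the marrow, where they are made, the blood, through which they travel, and the lung. The deposited estimated read counts summed to between 42045548 (blood replicate 3) and 56796219 (bone marrow replicate 2) per library. Between 11642 and 14584 genes had at least 10 reads. At this depth a floor of 3 reads was 0.0528 to 0.0714 CPM, the count scaled to the library's total. Intervals and floors cover counting error only. The counts of blood and lung were about 2 times the RSEM counts. If each fragment was counted 2 times, the intervals are too narrow and the bounds given as "at least" about 2 times too high. Levels are given in CPM after scaling by the trimmed mean of M-values, as mean ± SD over n = 3 libraries. Log2 fold changes are given as estimate ± SE. Gene positions are those of the mm10 build.

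The libraries separated by tissue along the first principal components, which held 51.5% and 22.4% of the variance. Lung replicate 3 lay apart from the other lung libraries, at 27.4 on the first component against 97.0 and 81.0, and it stood alone on the third component. Across genes, the correlation of log2 levels was 0.941 to 0.993 between libraries of the same tissue and 0.872 to 0.959 between tissues, where genes are not independent replicates. Transcripts typical of other cells also differed between replicates. Sftpc, the surfactant protein C gene of alveolar epithelium, stood at 505, 122 and 25.2 CPM in lung replicates 1, 2 and 3 and at 36.3 CPM in bone marrow replicate 3. Col3a1, a collagen gene of fibroblasts, stood at 449, 423 and 27.2 CPM in the same lung libraries. Cd79a, a B-cell receptor component, reached 105 and 96.8 CPM in blood replicates 1 and 2 against 16.1 CPM in blood replicate 3.

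**Figure D1:**
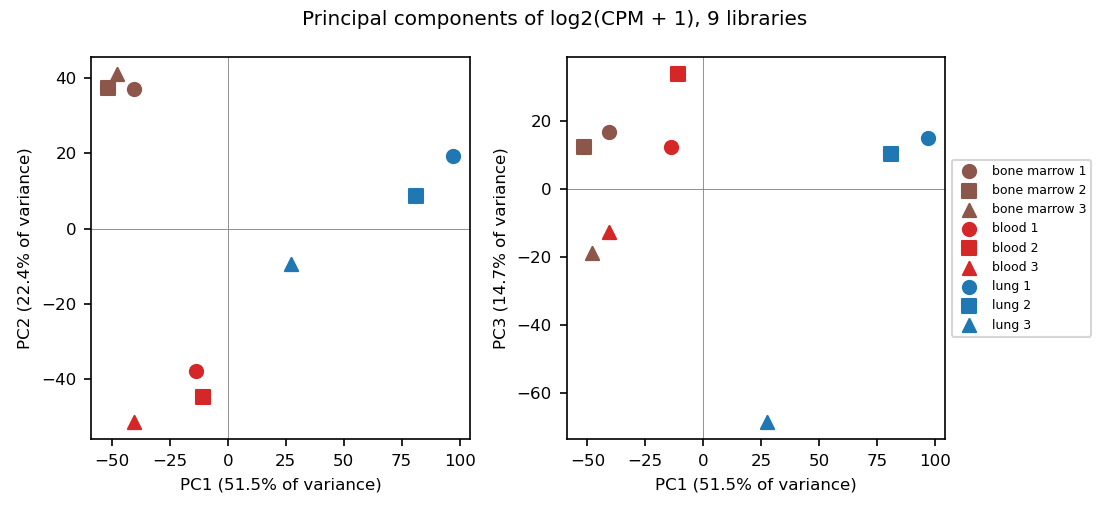
Principal components 1 against 2 (left) and 1 against 3 (right) of log2(CPM + 1) in the 9 libraries, with tissue as colour and replicate as symbol. Lung replicate 3 lies at 27.4 on component 1, between the other lung libraries and the rest.

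Of 13510 genes tested, 6223 differed among the 3 tissues by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Bone marrow was highest against both other tissues in 1256 genes, lung in 1039 and blood in 386 (620 with the replicate number as a block). Leaving out single libraries moved these counts by over 1.5 times. Genes highest in lung numbered 593 without bone marrow replicate 1 and 488 without bone marrow replicate 2. They numbered 689 without blood replicate 2 and 680 without blood replicate 3. Without lung replicate 1 they were 605, without lung replicate 2 635 and without lung replicate 3 1911. Genes highest in blood numbered 212, 141 and 102 without blood replicates 1, 2 and 3. They were 207, 169 and 218 without bone marrow replicates 1, 2 and 3, and 637 without lung replicate 3. Genes highest in bone marrow numbered 567, 504 and 680 without blood replicates 1, 2 and 3. They were 773 and 765 without bone marrow replicates 2 and 3.

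Neutrophils in blood held far lower levels of several granule protein transcripts than neutrophils in bone marrow. Ltf, which encodes the iron-binding granule protein lactoferrin (Entrez gene 17002, chromosome 9, 111019292 to 111042766), fell from 7162 ± 992 CPM in bone marrow to 123 ± 23.5 CPM in blood, a log2 fold change of -5.87 ± 0.30 (adjusted p = 2.00e-05) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Camp, the cathelicidin gene (Entrez gene 12796, chromosome 9, 109847377 to 109849456), and Ngp, which encodes neutrophilic granule protein (Entrez gene 18054, chromosome 9, 110419808 to 110423012), changed by -6.01 ± 0.35 and -6.01 ± 0.35 on the log2 scale. Mpo and Elane, which encode myeloperoxidase and neutrophil elastase of the primary granules, stood at 78.7 ± 76.6 and 21.6 ± 21.1 CPM in marrow and at 0.0727 ± 0.126 and 0.0563 ± 0.0300 CPM in blood, log2 fold changes of -10.10 ± 1.58 and -8.55 ± 1.17 (edgeR adjusted p = 0.00285 and 0.00137). Limma-voom did not call these 2 genes (adjusted p = 0.322 and 0.288). Some interferon-stimulated genes (11 of 41) and MHC class II list genes (7 of 17) were higher in blood, 2 lists without a call under an estimated correlation, as were Csf1, which encodes a macrophage growth factor, and Il1b, which encodes interleukin 1 beta.

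All 3 granule lists had a call by camera, and none under an estimated correlation. Of the secondary (specific) granule genes, 16 of 18 fell (17 adjusted over the list alone), with camera adjusted p = 9.61e-40, and adjusted p = 0.215 with an estimated correlation. Itgb2l and the surface protein gene Cd177 changed by -5.46 ± 0.29 and -4.56 ± 0.29. Of the primary (azurophil) granule genes, 7 of 12 fell (7 adjusted over the list alone, with camera adjusted p = 0.00284, and adjusted p = 0.404 with an estimated correlation). Limma-voom called 3 of them, and its list test gave adjusted p = 0.0504. Of the tertiary granule and secretory vesicle genes, 8 of 18 fell (10 adjusted over the list alone, with camera adjusted p = 2.44e-05, and adjusted p = 0.695 with an estimated correlation). Of the neutrophil identity genes, 2 of 25 rose and 13 fell (2 and 14 adjusted over the list alone), with camera adjusted p = 5.06e-13, and adjusted p = 0.630 with an estimated correlation. Ly6g, the surface antigen commonly used to sort mouse neutrophils, fell from 528 ± 134 CPM in bone marrow to 23.0 ± 1.78 CPM in blood, a log2 fold change of -4.52 ± 0.29 (adjusted p = 3.66e-05) by edgeR. The collagenase gene Mmp8 changed by -3.79 ± 0.33. Of the NADPH oxidase genes, 6 of 10 fell (7 adjusted over the list alone, with camera adjusted p = 6.98e-05, and adjusted p = 0.630 with an estimated correlation). Its catalytic subunit gene Cybb changed by -3.16 ± 0.29.

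Some genes of proliferation and metabolism were also lower in blood, in lists that camera called only with its preset correlation. Of the cell cycle genes, 1 of 45 rose and 20 fell (1 and 28 adjusted over the list alone, with camera adjusted p = 1.95e-05, and adjusted p = 0.759 with an estimated correlation). Limma-voom called 6 of the 45 and DESeq2 29. In this list the proliferation marker Mki67 changed by -4.21 ± 0.73, adjusted p = 0.00464 by edgeR. RSEM counts, read here for blood and lung only, put Mki67 at 0.0651 in lung against blood (edgeR adjusted p = 0.838) where the series table gave 3.67. Whether its level in blood or in lung differed between the counts is not shown. The fall from bone marrow to blood could therefore not be checked with RSEM counts. Of the hypoxia and glycolysis genes, 1 of 32 rose and 16 fell (2 and 17 adjusted over the list alone, with camera adjusted p = 0.000439, and adjusted p = 0.759 with an estimated correlation). Pgk1, which encodes phosphoglycerate kinase, fell furthest, at -2.14 ± 0.22. Of the oxidative phosphorylation genes, 18 of 46 fell (27 adjusted over the list alone, with camera adjusted p = 0.000748, and adjusted p = 0.759 with an estimated correlation). Of the growth factor and tissue remodelling genes, 2 of 37 rose and 10 fell (2 and 10 adjusted over the list alone, with camera adjusted p = 0.00705, and adjusted p = 0.684 with an estimated correlation). In the last list Lta4h, which encodes leukotriene A4 hydrolase, changed by -2.35 ± 0.12 and the metalloproteinase inhibitor gene Timp2 by -2.52 ± 0.26. The remaining genes of the 10 largest falls were Slc4a1, the red cell anion exchanger (-7.30 ± 1.46), Tmcc2 (-6.67 ± 1.30), Gpr27 (-6.47 ± 0.46), Adpgk, which encodes ADP-dependent glucokinase (-5.54 ± 0.27), and Chil5 (-5.53 ± 0.32). Limma-voom did not call Slc4a1 or Tmcc2 (adjusted p = 0.308 and 0.214). Of the erythroid genes, 9 of 16 fell (10 adjusted over the list alone, with camera adjusted p = 0.00999, and adjusted p = 0.759 with an estimated correlation). By limma-voom 1 of the 16 passed, with list adjusted p = 0.0741. Alas2, the haem synthesis enzyme of red cell precursors, stood at 198, 228 and 16.2 CPM in the marrow libraries and 179, 141 and 12.1 CPM in the blood libraries.

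Among the genes higher in blood, the largest rises included Amz1 (4.52 ± 0.33, adjusted p = 5.48e-05 by edgeR), the transcription factor gene Rfx2 (3.47 ± 0.25), the integrin gene Itga5 (3.71 ± 0.23), Cd244 (3.70 ± 0.31), Ccdc146 (3.51 ± 0.29), the cholesterol acyltransferase gene Soat2 (3.35 ± 0.25) and the metalloreductase gene Steap4 (3.30 ± 0.32). Of the interferon-stimulated genes, 11 of 41 rose and 2 fell (14 and 2 adjusted over the list alone, with camera adjusted p = 6.98e-05, and adjusted p = 0.759 with an estimated correlation). Slfn5 changed by 1.80 ± 0.31 and Ifitm1 by 1.67 ± 0.25. Of the NF-kB response genes, 8 of 33 rose and 3 fell (8 and 3 adjusted over the list alone, with camera adjusted p = 0.00668, and adjusted p = 0.766 with an estimated correlation). The prostaglandin synthase gene Ptgs2 stood at 1.97 ± 0.37. This list call was lost without blood replicate 1 (camera adjusted p = 0.0625). By edgeR, Csf1 rose from 128 ± 29.0 CPM in bone marrow to 931 ± 289.8 CPM in blood, a log2 fold change of 2.86 ± 0.43 (adjusted p = 0.00212). In edgeR's test Il1b rose from 1797 ± 320.3 CPM in bone marrow to 6120.2 ± 801 CPM in blood, a log2 fold change of 1.77 ± 0.33 (adjusted p = 0.00585).

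Several rises came with markers of other blood cells. Of the dendritic cell and MHC class II genes, 7 of 17 rose (12 adjusted over the list alone, with camera adjusted p = 0.000176, and adjusted p = 0.759 with an estimated correlation). Of the monocyte genes, 5 of 17 rose (8 and 1 adjusted over the list alone, with camera adjusted p = 0.00176, and adjusted p = 0.745 with an estimated correlation). Of the platelet genes, 6 of 18 rose and 2 fell (8 and 2 adjusted over the list alone, with camera adjusted p = 0.00999, and adjusted p = 0.759 with an estimated correlation). Of the B and plasma cell genes, 2 of 14 rose (none adjusted over the list alone, with camera adjusted p = 0.0278, and adjusted p = 0.845 with an estimated correlation). Limma-voom called 3 of the MHC class II list, 1 monocyte, 3 platelet and 0 B-cell genes, where edgeR had 5 B-cell genes at an unadjusted p under 0.05 and DESeq2 called 7. Ace, a marker of patrolling monocytes, rose by 4.91 ± 0.93, adjusted p = 0.00687 by edgeR, with 83.9, 59.3 and 13.1 CPM in blood replicates 1, 2 and 3. Fcer2a, a low-affinity IgE receptor gene of B cells, stood at 47.5, 45.5 and 7.79 CPM. Ciita, the MHC class II transactivator gene, stood at 28.7, 34.3 and 4.73 CPM, lowest in replicate 3 as was Cd79a. Fcer2a rose by 3.91 ± 0.90 and Ciita by 3.77 ± 0.86. EdgeR lost these calls without bone marrow replicate 2 (adjusted p = 0.0727 and 0.0698) and without bone marrow replicate 3 (adjusted p = 0.0634 and 0.0587). Limma-voom called none of Ace, Fcer2a and Ciita (adjusted p = 0.101, 0.199 and 0.220). The B-cell call was lost without bone marrow replicate 3 (camera adjusted p = 0.449) or blood replicates 1 and 2 (0.231 and 0.261). It was also lost by camera without lung replicates 1, 2 and 3 (0.144, 0.130 and 0.0636), and with upper-quartile scaling (0.0970). Of the fibroblast and smooth muscle genes, 2 of 21 fell (1 adjusted over the list alone, with camera adjusted p = 0.0359, and adjusted p = 0.845 with an estimated correlation). This call was absent without bone marrow replicate 3 (camera adjusted p = 0.276) and with the replicate block (0.106).

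The other lists had no call by camera between blood and bone marrow, with adjusted p from 0.0741 to 0.922. By edgeR's test, members passed as follows. Granulopoiesis transcription factors had 4 up and 4 down of 22 (4 and 5 adjusted over the list alone), and cytokines had 4 up and 2 down of 35 (4 and 2 adjusted over the list alone). Immediate early genes had 3 up and 4 down of 30 (4 and 4 adjusted over the list alone), and heat shock genes had 4 down of 18 (1 and 4 adjusted over the list alone). Chemotaxis receptors had 6 up and 8 down of 37 (6 and 10 adjusted over the list alone), and pattern recognition receptors had 7 up and 1 down of 34 (8 and 2 adjusted over the list alone). Apoptosis genes had 6 up and 5 down of 35 (7 and 7 adjusted over the list alone), and clock genes had 1 up of 19 (1 adjusted over the list alone). T and NK cells had 1 down of 22 (none adjusted over the list alone), and macrophages had 3 up and 2 down of 22 (4 and 3 adjusted over the list alone). Eosinophils and mast cells had 2 up and 3 down of 14 (3 and 5 adjusted over the list alone), and progenitors had 1 up and 4 down of 16 (1 and 4 adjusted over the list alone). Lung epithelium had 2 up and 2 down of 23 (2 and 2 adjusted over the list alone), and endothelium had 2 up and 3 down of 21 (2 and 4 adjusted over the list alone). Lung stromal signals had 1 down of 5 (1 adjusted over the list alone). The median differed in sign from the test for granulopoiesis transcription factors, cytokines, macrophages and apoptosis genes, as did the mean of the first 3, and the mean alone did for immediate early, chemotaxis, clock and eosinophil genes. None of the 81 ribosomal protein genes passed edgeR's test, where 3 had an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom none. In camera tests without blood replicate 1 the heat shock list passed (adjusted p = 0.00360), without blood replicate 2 the pattern recognition, T and NK cell, progenitor and endothelial lists (0.0288, 0.0170, 0.00449 and 0.0307). Without blood replicate 3 the ribosomal list passed (0.0171). The pattern recognition and progenitor lists passed without bone marrow replicate 3 (0.0495 and 0.0102). The progenitor list also passed without blood replicate 1 (0.0375), without lung replicate 3 (0.0496) and with DESeq2 size factors (0.0332).

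In all, edgeR called 2892 genes between blood and bone marrow, 1127 higher and 1765 lower in blood. The share higher was 39.0%, 52.6% with upper-quartile scaling and 62.1% with limma on the deposited FPKM. The replicates of the 2 tissues did not overlap in 6132 genes, 45.4% of those tested, where chance gives 10%. Among genes followed in every comparison, the alarmin gene S100a8 fell from 18339 ± 3201 CPM in bone marrow to 3667 ± 607 CPM in blood, a log2 fold change of -2.32 ± 0.32 (adjusted p = 0.00127) by edgeR. The chemokine receptor genes Cxcr2 and Cxcr4 and the adhesion gene Itgam did not pass, with log2 fold changes of 0.32 ± 0.35, 0.40 ± 0.28 and -0.93 ± 0.32. Itgam passed with the replicate block (-0.94, edgeR adjusted p = 0.0166), without lung replicate 1 (adjusted p = 0.0389) and without lung replicate 3 (adjusted p = 0.0110). The count was 1555, 1236 and 1499 without blood replicates 1, 2 and 3, and 1595 and 1665 without bone marrow replicates 2 and 3.

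**Figure D2:**
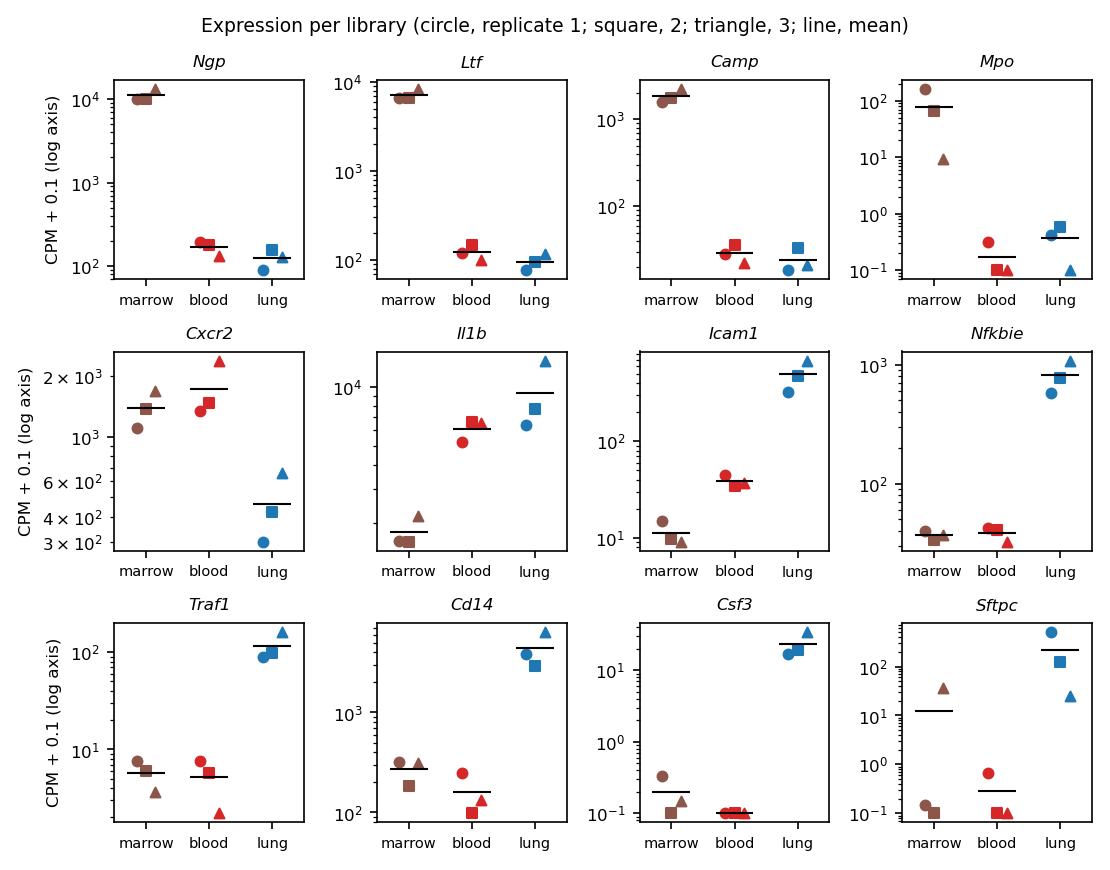
Level of 12 genes in each library, as CPM + 0.1 on log axes, with symbols for replicates and a line at the mean of each tissue. Ngp, Ltf and Camp are lower in all blood and lung libraries than in any marrow library, and Icam1, Nfkbie, Traf1 and Csf3 are highest in all 3 lung libraries.

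Of the NF-kB response genes tested, 22 of 33 were higher in neutrophils sorted from lung than in blood neutrophils, as were 12 of 35 cytokine and chemokine genes. Nfkbie, which encodes an NF-kB inhibitor, rose from 38.5 ± 5.39 CPM in blood to 811 ± 254 CPM in lung, a log2 fold change of 4.40 ± 0.27 (adjusted p = 0.000129) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Icam1, an adhesion molecule gene (Entrez gene 15894, chromosome 9, 21015940 to 21028814), rose from 38.5 ± 5.58 CPM in blood to 496 ± 182 CPM in lung, a log2 fold change of 3.69 ± 0.33 (adjusted p = 0.000242) by edgeR. Traf1, a signalling adaptor gene, rose by 4.52 ± 0.51. Csf3, which encodes the granulocyte colony-stimulating factor (Entrez gene 12985, chromosome 11, 98701313 to 98703629), had no reads in blood. It stood at 17.0, 19.3 and 34.2 CPM in lung replicates 1, 2 and 3, at least 1108-fold higher against a floor of 3 reads over the group. The lung libraries also held transcripts of lung epithelium, endothelium, fibroblasts and macrophages, at levels that differed between the lung libraries.

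Of the NF-kB response genes, 22 of 33 rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 fold change of 1.77 (camera adjusted p = 1.74e-21, and adjusted p = 0.404 with an estimated correlation). All 22 rising members lay above a log2 ratio of -1 between lung replicate 3 and lung replicate 1, with a median ratio of 0.70. Slc7a11, a cystine transporter gene, rose by 3.63 ± 0.31. Of the cytokine and chemokine genes, 12 of 35 rose and 2 fell (14 and 2 adjusted over the list alone, with camera adjusted p = 0.000249, and adjusted p = 0.695 with an estimated correlation). The neutrophil-attracting chemokine gene Cxcl1 changed by 6.56 ± 0.72 and Il1a, which encodes interleukin 1 alpha, by 4.50 ± 0.90. Here 4 of 12 rising genes lay below a log2 ratio of -1 between lung replicates 3 and 1. Of the apoptosis and survival genes, 15 of 35 rose and 8 fell (15 and 10 adjusted over the list alone, with camera adjusted p = 0.0174, and adjusted p = 0.759 with an estimated correlation). The risers included both the pro-apoptotic gene Bcl2l11 (2.84 ± 0.29) and the Bcl2a1 survival genes, whose near-identical copies make the split of reads uncertain. The apoptosis call was lost without blood replicate 1 (camera adjusted p = 0.0922), blood replicate 2 (0.179) or lung replicate 3 (0.311).

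Of the tertiary granule and secretory vesicle genes, 6 of 18 rose (6 adjusted over the list alone, with camera adjusted p = 0.0336, and adjusted p = 0.787 with an estimated correlation). Cd14, the lipopolysaccharide co-receptor gene, rose furthest, from 159 ± 79.0 CPM in blood to 4372 ± 1799 CPM in lung, a log2 fold change of 4.78 ± 0.49 (adjusted p = 0.000420) by edgeR. Cd93, a cell surface glycoprotein gene, rose by 3.11 ± 0.29. That list call was lost without bone marrow replicates 1, 2 or 3 (camera adjusted p = 0.0568, 0.0503 and 0.0610), blood replicate 2 (0.182) or lung replicate 3 (0.460). Of the granulopoiesis transcription factors, 4 of 22 rose and 9 fell (4 and 9 adjusted over the list alone, with camera adjusted p = 0.0499, and adjusted p = 0.695 with an estimated correlation). Rara, the retinoic acid receptor alpha gene, changed by -2.50 ± 0.22 and Cebpd by -2.09 ± 0.22. That call was lost with the replicate block (camera adjusted p = 0.0877), with DESeq2 size factors (0.0722). Camera also lost it without blood replicate 1 (0.106), lung replicate 1 (0.0793) or lung replicate 2 (0.0642). Of the interferon-stimulated genes, 2 of 41 rose and 12 fell (2 and 12 adjusted over the list alone, with camera adjusted p = 0.00347, and adjusted p = 0.818 with an estimated correlation). With lung replicate 3 as the only lung library camera lost this list (adjusted p = 0.904) and the transcription factors (0.292), and with a stromal marker score (the mean log2 level of the epithelium, endothelium and fibroblast lists) as a covariate the interferon test turned without passing (median -0.0782, adjusted p = 0.643). The deconjugase gene Usp18 changed by -1.66 ± 0.31, while Isg15, which encodes a ubiquitin-like protein, rose by 1.97 ± 0.29. The 10 largest falls held the adaptor gene Sla (-3.58 ± 0.32, adjusted p = 0.000242 by edgeR), Asb7 (-2.98 ± 0.16), Abhd15 (-2.97 ± 0.29), the DNA repair gene Xpc (-2.90 ± 0.33), the transcription factor gene Nfic (-2.84 ± 0.25) and Cep19 (-2.71 ± 0.34). They also held the histone gene Hist2h2aa2, 2390.2 (95% counting interval 818 to 11593) times higher in blood in the series table. This gene has near-identical copies, and its RSEM estimate differed by 0.20 on the log2 scale, edgeR adjusted p = 0.594, with no call.

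Transcripts of other lung cells were higher in the lung samples. Of the lung epithelium genes, 14 of 23 rose and 1 fell (17 and 2 adjusted over the list alone, with camera adjusted p = 6.98e-05, and adjusted p = 0.695 with an estimated correlation). The list had a median log2 fold change of 7.56, or 5.75 with genes lacking reads in blood held at their bound. Of the endothelium genes, 16 of 21 rose (19 adjusted over the list alone, with camera adjusted p = 3.26e-07, and adjusted p = 0.630 with an estimated correlation). Of the fibroblast and smooth muscle genes, 18 of 21 rose (20 adjusted over the list alone, with camera adjusted p = 1.35e-07, and adjusted p = 0.695 with an estimated correlation). Of the macrophage genes, 15 of 22 rose (15 and 1 adjusted over the list alone, with camera adjusted p = 8.52e-07, and adjusted p = 0.630 with an estimated correlation). Of the 5 tested lung stromal signal genes, 5 of 5 rose (5 adjusted over the list alone, with camera adjusted p = 0.000568, and adjusted p = 0.577 with an estimated correlation). The list has 12 genes, which together held 0.213, 0.284 and 0.309 CPM before scaling in the blood libraries and 101, 54.3 and 30.5 CPM in lung. The tested genes thus passed the filter for low counts mainly through lung, so their rise and the list call were nearly fixed in advance. Between lung replicates 3 and 1, 4 of these 5 lay below a log2 ratio of -1, while Csf3 lay at 1.01. Of the progenitor genes, 4 of 16 rose (4 adjusted over the list alone, with camera adjusted p = 0.0181, and adjusted p = 0.759 with an estimated correlation). This call was lost with upper-quartile scaling (camera adjusted p = 0.0584). Lung replicate 3 alone also lost it (camera adjusted p = 0.610). For the epithelium, endothelium, fibroblast, macrophage and lung stromal signal lists limma-voom called 7, 10, 2, 5 and 1 genes, fewer than edgeR in each list, while the list calls were kept. Together 57 of 63 rising epithelial, endothelial, fibroblast and macrophage genes lay below a log2 ratio of -1 between lung replicates 3 and 1, with a median ratio of -2.98. The elastin gene Eln was at least 3649.8-fold higher in lung than in blood. The club cell secretoglobin gene Scgb1a1 rose by 11.33 ± 2.69, and the surfactant genes Sftpc and Sftpa1 by 10.21 ± 2.87 and 10.23 ± 2.71. The complement gene C7 was 2114 (95% counting interval 585 to 17464) times higher in lung and the protease gene Htra3 1774 (95% counting interval 491 to 14650.3) times. The matrix genes Col14a1, Ltbp4 and Dpt rose by 10.19 ± 2.15, 9.80 ± 2.20 and 9.78 ± 2.53. Of these 10 largest rises, 7 lost edgeR's call without at least 1 library, with adjusted p from 0.0502 to 0.103. Eln, Scgb1a1, C7, Sftpa1, Sftpc, Ltbp4 and Dpt lost it without blood replicate 2 (edgeR adjusted p = 0.0644, 0.0625, 0.0635, 0.0815, 0.0998, 0.0502 and 0.0750). Without blood replicate 3 edgeR gave them adjusted p = 0.0633, 0.0617, 0.0626, 0.0810, 0.103, 0.0513 and 0.0750. All but Ltbp4 also lost it without blood replicate 1 (edgeR adjusted p = 0.0605, 0.0658, 0.0676, 0.0820, 0.0822 and 0.0705). Eln, Sftpa1, Sftpc and Dpt lost it without lung replicate 1 (edgeR adjusted p = 0.0574, 0.0647, 0.0692 and 0.0555). Eln also lost it without lung replicate 2 (0.0541) and with the replicate block (0.0831). With lung replicate 3 as the only lung library, Csf3 kept the call and the others lost it. Scgb1a1, Sftpc and Eln still stood at 23.7, 25.2 and 4.12 CPM there, against 172, 505 and 120 CPM in lung replicate 1. In blood replicate 1 they stood at 0.109, 0.567 and 0 CPM, with no reads in the other blood libraries. Limma-voom also called only Csf3 of the 10, with adjusted p from 0.130 (Scgb1a1) to 0.385 (Htra3) for the others.

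Heat shock, growth factor, cell cycle and ribosomal protein lists were also called between lung and blood. Of the heat shock and chaperone genes, 13 of 18 rose (14 adjusted over the list alone, with camera adjusted p = 3.04e-06, and adjusted p = 0.630 with an estimated correlation). Hspb1 rose by 6.01 ± 1.07, and 9 of the 13 rising genes lay below a log2 ratio of -1 between lung replicates 3 and 1, where 40.9% of all 1780 rising genes did. Of the growth factor and tissue remodelling genes, 17 of 37 rose and 1 fell (19 and 3 adjusted over the list alone, with camera adjusted p = 2.07e-05, and adjusted p = 0.404 with an estimated correlation). Here 9 of 17 rising genes lay below that ratio. Of the cell cycle genes, 9 of 45 rose and 2 fell (7 and 2 adjusted over the list alone, with camera adjusted p = 0.00759, and adjusted p = 0.845 with an estimated correlation). Mki67 rose by 3.67 ± 0.71, adjusted p = 0.00617 by edgeR, and 6 of 9 rising genes, Mki67 not among them, lay below that ratio. The Mki67 call was absent with RSEM counts (log2 fold change 0.0651, edgeR adjusted p = 0.838). With lung replicate 3 as the only lung library its fold was kept at 3.68, with edgeR adjusted p = 0.0522. In that fit the cell cycle list had no call and a median below 0 (camera adjusted p = 0.593). Limma-voom called 7 heat shock, 11 growth factor and 6 cell cycle genes, where edgeR called 13, 18 and 11. It did not call Hspb1 (limma-voom adjusted p = 0.121). Of the ribosomal protein genes, 17 of 81 rose (1 adjusted over the list alone, with camera adjusted p = 4.87e-07, and adjusted p = 0.759 with an estimated correlation). The stromal marker score as a covariate ended this call (camera adjusted p = 0.554). Every lung library scored above all others (lung 4.38, 3.65 and 1.85, others 0.934 to 1.78), so the covariate also removes part of the tissue difference. DESeq2 called 56 of the 81 ribosomal protein genes and limma-voom 16. Rpl23 rose by 0.99 ± 0.17. The erythroid list had no call between lung and blood (camera adjusted p = 0.242), although the 10 largest falls held Alas2 at -5.10 ± 1.35, the beta-globin gene Hbb-b2, whose reads could fall on near-identical copies, at -4.97 ± 1.29 and Bpgm at -3.07 ± 0.91. These 3 calls were lost without blood replicate 1 (edgeR adjusted p = 0.0548, 0.0516 and 0.0873). They were also lost by edgeR without lung replicate 1 (adjusted p = 0.0579, 0.0516 and 0.0831) or lung replicate 2 (0.0651, 0.0618 and 0.0846). Without blood replicate 2 edgeR lost Alas2 and Bpgm (adjusted p = 0.0535 and 0.0799), and without lung replicate 3 Bpgm (adjusted p = 0.0755). All 3 were lost with lung replicate 3 as the only lung library, although Alas2 and Hbb-b2 were lower there, at 0.422 and 8.44 CPM. They stood at 4.98 and 72.3 CPM in lung replicate 1 and at 4.23 and 58.3 CPM in lung replicate 2. Limma-voom did not call Alas2 or Bpgm (adjusted p = 0.172 and 0.197).

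**Figure D3:**
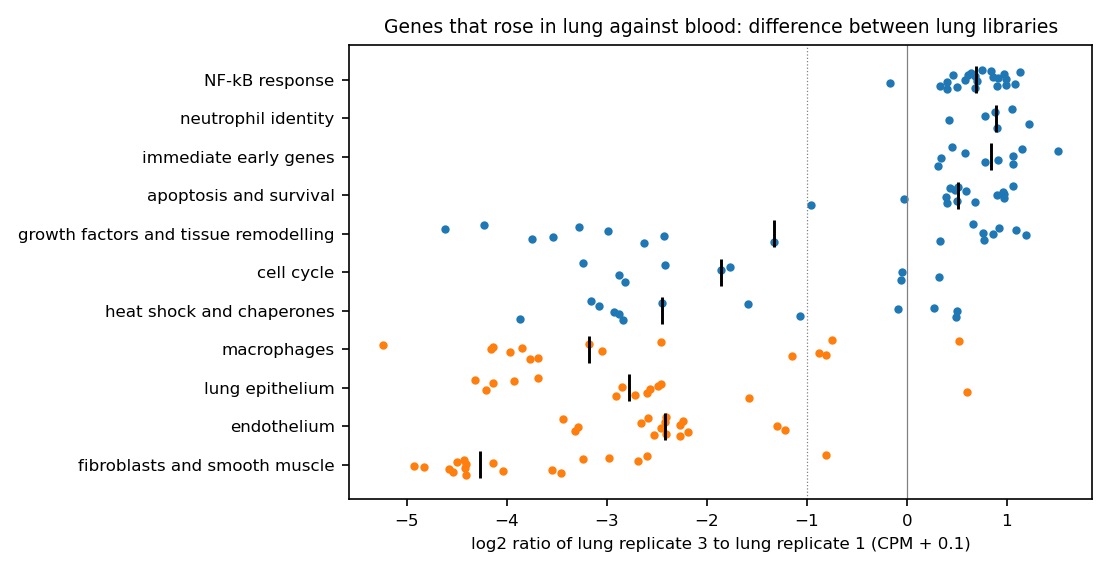
Log2 ratio of lung replicate 3 to lung replicate 1, with 0.1 CPM added to both, for each gene that rose in lung against blood, by gene list, with cell type lists in orange and medians as black lines. Rising NF-kB response genes have a median of 0.70 and rising fibroblast genes a median of -4.27.

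Lists without a call by camera between lung and blood had adjusted p from 0.0879 to 0.922. By edgeR's test, members passed as follows. Neutrophil identity had 6 up and 2 down of 25 (6 and 3 adjusted over the list alone), and primary granules had 2 up of 12 (2 adjusted over the list alone). Secondary granules had 2 up and 2 down of 18 (1 and 2 adjusted over the list alone), and immediate early genes had 10 up and 7 down of 30 (10 and 8 adjusted over the list alone). Hypoxia and glycolysis had 7 up and 5 down of 32 (8 and 6 adjusted over the list alone), and oxidative phosphorylation had 4 up and 2 down of 46 (3 and none adjusted over the list alone). Chemotaxis receptors had 6 up and 5 down of 37 (7 and 7 adjusted over the list alone), and pattern recognition had 7 up and 4 down of 34 (7 and 5 adjusted over the list alone). Clock genes had 1 up of 19 (1 adjusted over the list alone), and B cells had 1 up of 14 (none adjusted over the list alone). Monocytes had 1 down of 17 (none adjusted over the list alone), and eosinophils and mast cells had 1 up of 14 (1 adjusted over the list alone). Erythroid cells had 1 up and 2 down of 16 (1 and 2 adjusted over the list alone), and platelets had 1 up and 2 down of 18 (1 and none adjusted over the list alone). The neutrophil identity list had a median of -0.12 while its mean and test pointed up, and G0s2, a lipolysis inhibitor gene, rose by 3.43 ± 0.30. The median also differed in sign from the mean for immediate early and chemotaxis genes, whose tests pointed up, and for hypoxia and glycolysis genes, whose test pointed down. Nr4a3, an orphan nuclear receptor gene, rose by 5.96 ± 1.08, and the hexokinase gene Hk2 changed by -2.33 ± 0.13. No gene of the NADPH oxidase, T and NK cell, or dendritic cell and MHC class II lists passed edgeR's test. At an unadjusted p under 0.05 edgeR called 1 of 10, 1 of 22 and 1 of 17. DESeq2 called 1 T and NK cell gene and 2 MHC class II list genes and none of the oxidase list, and limma-voom called none in the 3 lists. The erythroid list passed with the replicate block (camera adjusted p = 0.00425) and without blood replicate 3 (0.0141). The T and NK cell list passed with the block (0.0417) and without blood replicate 2 (0.00878). Other camera calls gained were the MHC class II list without blood replicate 2 (adjusted p = 0.0172) or lung replicate 3 (0.0272) and the eosinophil list without blood replicate 2 (0.0327). The clock and platelet lists passed without blood replicate 1 (0.0342 and 0.00710) and the monocyte list without blood replicate 3 (0.0163). Oxidative phosphorylation passed without lung replicate 2 (0.0352) or with upper-quartile (0.0174) or DESeq2 scaling (0.0452).

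In all, 3900 genes passed edgeR's test between lung and blood, 1780 higher and 2120 lower in lung. The share higher was 45.6%, 55.9% with upper-quartile scaling, 56.9% with DESeq2 size factors and 26.6% with limma on the deposited FPKM. Replicates did not overlap in 5622 genes (41.6%, chance 10%). Cxcr2 fell from 1736 ± 576 CPM in blood to 461 ± 184 CPM in lung, a log2 fold change of -1.91 ± 0.36 (adjusted p = 0.00501) by edgeR. The Cxcr2 call was lost with lung replicate 3 as the only lung library, a group of 1 library. Cxcr2 stood at 661 CPM there, below the 1345, 1464 and 2397 CPM of blood replicates 1, 2 and 3. Cxcr4, Ly6g, S100a8, Itgam, Ltf and Il1b did not pass, with log2 fold changes of 0.15 ± 0.28, -0.21 ± 0.25, -0.14 ± 0.30, -0.34 ± 0.32, -0.36 ± 0.25 and 0.60 ± 0.32. Mpo stood at 0.0727 ± 0.126 CPM in blood and 0.268 ± 0.244 CPM in lung. Itgam passed without lung replicate 3 (-0.81, edgeR adjusted p = 0.0254). Cxcr4 turned sign without blood replicate 2 (-0.0352) or lung replicate 3 (-0.15). S100a8 turned sign without blood replicate 3 (0.0443) or lung replicate 1 (0.0191) and with upper-quartile scaling. The count of changed genes was 2527, 2338 and 1922 without blood replicates 1, 2 and 3 and 5852 without lung replicate 3. With lung replicate 3 as the only lung library it was 2033.

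Against bone marrow, 16 of 18 secondary granule genes were lower in lung neutrophils, and 24 of 33 NF-kB response genes were higher. Of the tertiary granule genes 10 of 18 were lower and 4 higher, and of the primary 6 of 12 lower and 3 higher. Camera called the secondary granule and NF-kB lists, and neither under an estimated correlation. It did not call the tertiary and primary lists (camera adjusted p = 0.194 and 0.242). The test fry called the primary list down (fry adjusted p = 0.0162) and not the tertiary list (0.108). In lung against blood, where camera had no call, fry called the primary list up (fry adjusted p = 0.0180). Ltf fell from 7162 ± 992 CPM in bone marrow to 95.4 ± 20.2 CPM in lung, a log2 fold change of -6.23 ± 0.31 (adjusted p = 9.14e-06) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Camp and Ngp changed by -6.26 ± 0.35 and -6.45 ± 0.36. Icam1 rose from 11.1 ± 3.32 CPM in bone marrow to 496 ± 182 CPM in lung, a log2 fold change of 5.48 ± 0.36 (adjusted p = 2.27e-05) by edgeR. Nr4a3 and the kinase phosphatase gene Dusp16 rose by 5.59 ± 1.06 and 6.72 ± 0.39, and Csf3 by 7.93 ± 0.97. Cebpe, a transcription factor gene of granulocyte maturation, changed by -3.84 ± 0.27.

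Of the secondary granule genes, 16 of 18 fell (16 adjusted over the list alone, with camera adjusted p = 3.07e-26, and adjusted p = 0.234 with an estimated correlation). Of the neutrophil identity genes, 5 of 25 rose and 15 fell (5 and 15 adjusted over the list alone, with camera adjusted p = 1.16e-05, and adjusted p = 0.759 with an estimated correlation). Of the NADPH oxidase genes, 4 of 10 fell (5 adjusted over the list alone, with camera adjusted p = 0.00540, and adjusted p = 0.695 with an estimated correlation). Cd177, Ly6g and Cybb changed by -5.48 ± 0.30, -4.73 ± 0.29 and -3.62 ± 0.30. Of the hypoxia and glycolysis genes, 5 of 32 rose and 16 fell (7 and 16 adjusted over the list alone, with camera adjusted p = 0.00248, and adjusted p = 0.759 with an estimated correlation). Hk2 changed by -2.51 ± 0.13 and Pgk1 by -2.29 ± 0.22. Of the erythroid genes, 11 of 16 fell (13 adjusted over the list alone, with camera adjusted p = 0.00508, and adjusted p = 0.759 with an estimated correlation). By limma-voom 1 of the 16 passed, with list adjusted p = 0.0621. With lung replicate 3 as the only lung library camera lost the neutrophil identity, NADPH oxidase and glycolysis lists (adjusted p = 0.0854, 0.0980 and 0.429), as it did with the stromal marker score (0.0568, 0.0927 and 0.208). The largest falls also included Mpo (-8.12 ± 1.39, adjusted p = 0.00215 by edgeR), Slc4a1 (-9.43 ± 1.66), Gpr27 (-6.42 ± 0.46), Itgb2l (-5.98 ± 0.29) and the platelet glycoprotein gene Gp1bb (-5.71 ± 1.10). Elane was 3166 (95% counting interval 568 to 125112) times higher in marrow, and Hist2h2aa2, with its near-identical copies, 3671 (95% counting interval 1256 to 17806) times. All 10 kept edgeR's call in each of the 9 fits that left out 1 library, but with lung replicate 3 as the only lung library Slc4a1 and Gp1bb lost it (adjusted p = 0.0669 and 0.135). Limma-voom did not call Mpo, Slc4a1, Gp1bb, Elane or Hist2h2aa2 (adjusted p = 0.199, 0.347, 0.117, 0.197 and 0.0577).

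Of the NF-kB response genes, 24 of 33 rose and 1 fell (28 and 1 adjusted over the list alone), median 2.12 (camera adjusted p = 1.74e-21, and adjusted p = 0.423 with an estimated correlation). Of the cytokine genes, 18 of 35 rose and 3 fell (20 and 3 adjusted over the list alone, with camera adjusted p = 0.000340, and adjusted p = 0.695 with an estimated correlation). Csf1 rose by 3.26 ± 0.44. Bcl2a1d, a survival gene with near-identical copies, rose by 5.16 ± 0.44. Of the dendritic cell and MHC class II genes, 14 of 17 rose (14 adjusted over the list alone, with camera adjusted p = 6.98e-05, and adjusted p = 0.759 with an estimated correlation). The class II gene H2-Eb1 rose by 4.33 ± 0.80, and H2-Aa stood at 476, 346 and 155 CPM in lung replicates 1, 2 and 3. Of the ribosomal protein genes, 35 of 81 rose (42 adjusted over the list alone, with camera adjusted p = 6.92e-07, and adjusted p = 0.759 with an estimated correlation). DESeq2 called 62 of the 81 and limma-voom 30. Of the heat shock genes, 12 of 18 rose (12 adjusted over the list alone, with camera adjusted p = 0.00999, and adjusted p = 0.759 with an estimated correlation). Of the macrophage genes, 18 of 22 rose (18 and 1 adjusted over the list alone, with camera adjusted p = 6.92e-07, and adjusted p = 0.630 with an estimated correlation). Of the lung epithelium genes, 9 of 23 rose (9 adjusted over the list alone, with camera adjusted p = 0.00471, and adjusted p = 0.759 with an estimated correlation). Of the endothelium genes, 12 of 21 rose and 1 fell (17 and 1 adjusted over the list alone, with camera adjusted p = 0.000573, and adjusted p = 0.759 with an estimated correlation). Of the fibroblast genes, 14 of 21 rose and 1 fell (17 and 1 adjusted over the list alone, with camera adjusted p = 0.00127, and adjusted p = 0.759 with an estimated correlation). Of the lung stromal signal genes, 2 of 5 rose (5 adjusted over the list alone, with camera adjusted p = 0.0233, and adjusted p = 0.630 with an estimated correlation). This call was lost with the block (camera adjusted p = 0.0970) and with upper-quartile scaling (0.0710). Against marrow, too, none of this list's genes reached a mean of 5 CPM outside lung, so the filter favoured a rise. With lung replicate 3 alone camera lost the heat shock, epithelium, endothelium, fibroblast and lung stromal signal lists (adjusted p = 0.122, 0.122, 0.0656, 0.250 and 0.212). The stromal marker score ended the calls of the heat shock, lung stromal signal and ribosomal lists (camera adjusted p = 0.288, 0.205 and 0.0835), and is no test of the 3 lists it is made of. The score was also higher in every lung library than in any other, so these losses do not separate stromal RNA from tissue. Limma-voom called 4 heat shock, 7 macrophage, 6 epithelium, 9 endothelium, 4 fibroblast and 1 stromal signal genes. The carbonic anhydrase gene Car4, expressed by lung endothelium and alveolar macrophages, rose by 6.93 ± 1.57. Plet1, Krt19, Inmt and Mgp, known from epithelium or stroma, rose by 5.59 ± 1.22, 5.34 ± 1.60, 5.26 ± 1.57 and 5.22 ± 1.79. Krt19, Inmt and Mgp lost edgeR's call without bone marrow replicate 1 (adjusted p = 0.0947, 0.0869 and 0.101) and bone marrow replicate 2 (0.0692, 0.0597 and 0.108). The same calls were lost by edgeR without lung replicate 1 (adjusted p = 0.0720, 0.104 and 0.157) and lung replicate 2 (0.0825, 0.0537 and 0.0866). With the replicate block edgeR gave adjusted p = 0.138, 0.0727 and 0.107 for the 3 genes. Mgp also lost it without blood replicates 1, 2 or 3 (edgeR adjusted p = 0.0711, 0.0713 and 0.0609). EdgeR lost the calls with lung replicate 3 as the only lung library for Car4, Plet1, Krt19, Inmt and Mgp (adjusted p = 0.219, 0.125, 0.579, 0.453 and 0.594). Limma-voom called none of Car4, Plet1, Krt19, Inmt and Mgp, with adjusted p from 0.125 (Plet1) to 0.279 (Car4).

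Lists without a call by camera between lung and bone marrow had adjusted p from 0.0526 to 0.774. By edgeR's test, members passed as follows. Primary granules had 3 up and 6 down of 12 (3 and 6 adjusted over the list alone), and tertiary granules had 4 up and 10 down of 18 (5 and 10 adjusted over the list alone). The cell cycle had 3 down of 45 (2 adjusted over the list alone), and granulopoiesis transcription factors had 3 up and 8 down of 22 (3 and 8 adjusted over the list alone). Immediate early genes had 8 up and 6 down of 30 (8 and 6 adjusted over the list alone), and interferon-stimulated genes had 5 up and 6 down of 41 (5 and 5 adjusted over the list alone). Oxidative phosphorylation had 8 down of 46 (7 adjusted over the list alone), and chemotaxis receptors had 7 up and 11 down of 37 (7 and 11 adjusted over the list alone). Pattern recognition had 13 up and 8 down of 34 (14 and 8 adjusted over the list alone), and apoptosis had 12 up and 13 down of 35 (12 and 13 adjusted over the list alone). Growth factors had 15 up and 7 down of 37 (15 and 8 adjusted over the list alone), and clock genes had 1 up of 19 (none adjusted over the list alone). B cells had 2 up of 14 (none adjusted over the list alone), and monocytes had 7 up and 1 down of 17 (7 and 1 adjusted over the list alone). Eosinophils had 3 up and 4 down of 14 (3 and 4 adjusted over the list alone), and progenitors had 3 up and 2 down of 16 (3 and 2 adjusted over the list alone). Platelets had 5 up and 2 down of 18 (5 and 2 adjusted over the list alone). Among them Klf2 and Rhob changed by -3.11 ± 0.28 and -3.48 ± 0.33, the sphingosine phosphate receptor gene S1pr4 by -3.49 ± 0.29, and the lectin gene Clec4n by 4.64 ± 0.45. The eosinophil list had a median above 0, a mean below 0 and a test pointing up, and the progenitor list a median below 0 with mean and test pointing up. No T or NK cell gene passed edgeR's test, where 1 of 22 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1. With the replicate block the B-cell and monocyte lists passed (camera adjusted p = 0.00705 and 0.0173). They also passed by camera without bone marrow replicate 1 (0.0299 and 0.0421), and the B-cell list without lung replicate 3 (0.0465). Other camera calls gained were the primary granule, cell cycle and apoptosis lists without bone marrow replicate 3 (adjusted p = 0.0206, 0.00642 and 0.0260). The cell cycle list passed without blood replicates 1, 2 or 3 (0.0324, 0.0281 and 0.0300), and the tertiary granule list without lung replicate 3 (0.0113). The apoptosis and pattern recognition lists passed without lung replicate 1 (0.00836 and 0.0141) or lung replicate 2 (0.00681 and 0.0329). The apoptosis list also passed with upper-quartile scaling (camera adjusted p = 0.00733).

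**Figure D4:**
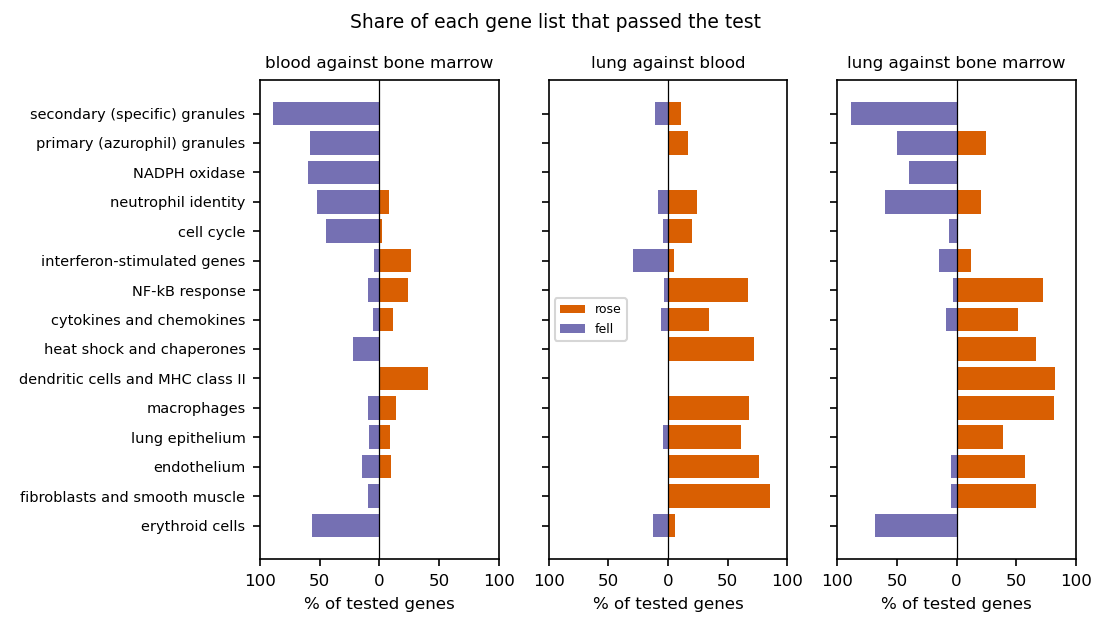
Percent of the tested genes of 15 lists that rose (right, orange) or fell (left, purple) by edgeR in each comparison. Secondary granule genes fell for 16 of 18 genes in blood and in lung against bone marrow, and 22 of 33 NF-kB response genes rose in lung against blood.

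In all, 5158 genes passed edgeR's test between lung and bone marrow, 2108 higher and 3050 lower in lung. The share higher was 40.9%, 59.3% with upper-quartile scaling and 52.0% with DESeq2 size factors. Replicates did not overlap in 6614 genes (49.0%, chance 10%). Il1b rose from 1797 ± 320.3 CPM in bone marrow to 9299 ± 3887 CPM in lung, a log2 fold change of 2.37 ± 0.34 (adjusted p = 0.000724) by edgeR. Cxcr2 fell from 1388 ± 292 CPM in bone marrow to 461 ± 184 CPM in lung, a log2 fold change of -1.59 ± 0.35 (adjusted p = 0.00769) by edgeR. The Cxcr2 call was lost with lung replicate 3 as the only lung library (edgeR adjusted p = 0.234). Itgam changed by -1.28 ± 0.32, adjusted p = 0.0140, and S100a8 by -2.47 ± 0.32, adjusted p = 0.000447 by edgeR, while Cxcr4 and Mki67 did not pass, with log2 fold changes of 0.55 ± 0.28 and -0.53 ± 0.63. Cxcr4 passed with upper-quartile scaling (0.85, edgeR adjusted p = 0.0173). Itgam lost the call without blood replicates 1, 2 or 3 (edgeR adjusted p = 0.0687, 0.0663 and 0.0575), without lung replicate 2 (0.0546) and with DESeq2 size factors (0.0512). The count was 3258 without bone marrow replicate 2 and 3120 with lung replicate 3 as the only lung library.

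Across the 3 comparisons, 48 of 99 list tests passed with camera's preset correlation between genes. With a correlation estimated for each list, none passed after adjustment and 7 had an unadjusted p under 0.05. The test fry, which tests whether a list's genes move on balance one way, called 32, of which 29 were also camera calls. Upper-quartile scaling moved the median log2 fold change of all genes by 0.15, 0.16 and 0.32 in blood against bone marrow, lung against blood and lung against bone marrow, and DESeq2 size factors moved it by 0.13 in the last. Of 4 tested sex-linked genes, Ddx3y, a Y-chromosome gene present in every library, rose in lung against blood and against bone marrow and did not pass in blood against bone marrow.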

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

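All tests in this part were chosen after the results they bear on had been seen.

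The RSEM files of blood and lung hold genes that the series table lacks, and these stood above the level that 0 reads allow in every library, outside the comparisons above. Mitochondrially encoded genes took 0.156 ± 0.103% of counts in blood and 0.465 ± 0.299% in lung (mean ± SD, n = 3), and lung replicate 3, at 0.121%, lay below blood replicates 1 and 2 (0.141% and 0.266%). By edgeR on RSEM counts 1 of 13 rose in lung, 10 had an unadjusted p under 0.05, and 0 to 8 rose with 1 library left out. The immunoglobulin genes Igkc and Ighm stood at 96.4 ± 66.5 and 504 ± 155 CPM (RSEM counts) in blood and at 152 ± 133 and 481 ± 279 in lung. The T-cell receptor genes Trac and Trbc2 stood at 4.63 ± 5.23 and 8.24 ± 10.2 in blood, most of it in blood replicate 2 (replicates 1 and 3 at 1.89 and 1.35 for Trac and 2.20 and 2.53 for Trbc2), and at 7.67 ± 5.67 and 11.5 ± 8.93 in lung. Igkc, Ighm, Trac and Trbc2 did not pass between lung and blood (edgeR adjusted p = 0.633, 0.930, 0.524 and 0.689), nor with any 1 library left out.

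Epithelial, endothelial, fibroblast and macrophage genes were higher in the lung libraries. Expression by the lung neutrophils alike in every mouse is argued against by 90.5% of the rising members lying below a log2 ratio of -1 between lung replicates 3 and 1, a wording narrowed after the values were seen. RNA of other lung cells in the sorted samples may explain them, since these genes had a median log2 ratio of -2.98 while rising neutrophil identity genes had 0.89. A neutrophil sort would remove such cells, yet Sftpc and Col3a1 reached 505 and 449 CPM in lung replicate 1. Of the tested epithelial, endothelial, fibroblast and macrophage genes, 6, 5, 8 and 7 reached a mean of 5 CPM in marrow or blood. The marrow mean includes replicate 3, where Sftpc stood at 36.3 CPM against 0.0477 and 0 CPM in marrow replicates 1 and 2, which raises these counts. Of the 4 lists 0, 3, 0 and 1 genes stand in another list. Expression by neutrophils that varies from mouse to mouse stays open.

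NF-kB response genes were higher in lung than in blood, where 7 of the 33 genes stand in another list and 31 reach 5 CPM in marrow or blood. RNA of lung structural cells and macrophages as the source is argued against by a median log2 ratio of 0.696 between lung replicates 3 and 1. The list's median stood at least 1.69 above that of all genes under 4 scalings. A scaling shifts all genes nearly alike, so trying 4 of them could not test scaling as a source. The rise over other genes is a difference that scaling hardly moves. Handling of lung tissue before the sort cannot be told apart from an effect of the lung itself, because tissue and handling coincide in the design, and 10 immediate early genes rose while 7 fell. A biological difference between lung and blood neutrophils is therefore also open.

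Bone marrow replicate 3 held lung-type transcripts, with Sftpc at 36.3 CPM. Reads from a sorted lung library are argued against by a median excess of 1.00% of lung replicate 1 (quartiles -0.634 to 2.50) over 12 genes high in lung neutrophil libraries, a set widened after a stricter one had left 3 genes with a median of 0.154%. Stromal cells of the marrow itself are argued against by the epithelial excess of 7.39%. RNA of other lung cells in this sample may explain the transcripts, with a median excess of 5.91% over 17 epithelial, endothelial and fibroblast genes and 2.82% for the 2 endothelial ones. The design gives no biological explanation to test.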

How the results depend on the processing

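The marker score covariates, the lung replicate 3 fit, the fit of replicates 1 and 2, and the RSEM counts were chosen after the data had been seen, and the other alternatives before.

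Leaving out 1 library at a time gave 1236 to 3965 changed genes in blood against bone marrow, 1922 to 5852 in lung against blood and 3258 to 6984 in lung against bone marrow. It gave 4789 to 8397 genes that differ among the 3 tissues, 488 to 1911 highest in lung, 102 to 637 highest in blood and 504 to 1601 highest in bone marrow. With 1 library left out, fewer samples remain, and counts rose where lung replicate 3 was left out.

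With the replicate number as a block, genes highest in blood numbered 620 and the pairwise counts were 3990, 4751 and 5973 in the order above. Besides the block values given in the report, the block ended the calls of H2-Aa (edgeR adjusted p = 0.0862) and H2-Ab1 (0.101) in blood against bone marrow, Sftpd (0.0855) in lung against blood, and Marco (0.0667), Tek (0.0545) and Dcn (0.111) in lung against bone marrow. It changed no other call of a named gene or list.

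Other counts moved by over 1.5 times, and the cause was not tested. Without a filter 774 genes were highest in bone marrow. The DESeq2 test gave 1616 highest in lung, and a fit of only the 6 libraries compared gave 614. Limma on the deposited FPKM tested only 4208 genes, those with a mean of at least 10. It gave 2497 changed genes in lung against blood, 2586 in lung against bone marrow and 3206 among the 3 tissues. Of these 4208 genes 489, 740 and 575 were highest in lung, blood and bone marrow. An absolute log2 fold change of at least 1 left 1755, 2452 and 3393 genes, by construction fewer. The stromal marker score as a covariate gave 1378 and 2989 in the lung comparisons, with 509 highest in lung and 186 in blood. Because every lung library scored above all others, calls lost or turned under it do not show stromal RNA as their source. The B-cell score gave 4920, 6032 and 1000 for blood against bone marrow, lung against blood and highest in blood. Lung replicate 3 alone as the lung group, assumed to vary like the other groups, gave 2033 and 3120 in the lung comparisons and 806 highest in bone marrow. Replicates 1 and 2 only gave 6062 and 7780 in the lung comparisons and 2362 highest in lung.

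Called genes shared with another setting kept their sign, except 1 under the stromal score and 1 with RSEM counts, both in lung against blood. Among values that reversed in lung against blood, the stromal score and lung replicate 3 alone gave 0.28 and 0.41 for Ly6g, 0.46 and 0.51 for S100a8, and 0.55 and 0.43 for Itgam. S100a8 was also at 0.0008 with upper-quartile scaling and 0.0443 and 0.0191 without blood replicate 3 and lung replicate 1 (down to -0.50 without lung replicate 3). Cxcr4 was at -0.0027 with FPKM and -0.0352 and -0.15 without blood replicate 2 and lung replicate 3 (up to 0.37 without blood replicate 3). Mpo was at -4.72 and Ltf at 0.11 in lung replicate 3 alone, Myc at -0.61 with the stromal score, and Hist2h2aa2 at 0.20 with RSEM counts. Medians that reversed in lung against blood were the cell cycle at -0.39 and -0.39 and B cells at -3.16 and -2.59 with the stromal score and in lung replicate 3 alone, and the test of interferon-stimulated genes with the stromal score (median -0.0782). The cause was not tested. A further 110 list tests changed direction without passing either way.

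Of 165 named gene results and 99 list tests, limma-voom ended 47 gene and 10 list calls and gave 0 and 1 new ones. The stromal score ended 47 gene and 13 list calls and gave 1 and 8, the B-cell score 12 gene and 5 list calls and gave 6 and 8, and lung replicate 3 alone 39 gene and 12 list calls and gave 3 and 9. The DESeq2 test ended 1 gene and 2 list calls and gave 0 and 3. The list calls ended in lung replicate 3 alone were B cells in blood against bone marrow (camera adjusted p = 0.116), transcription factors, interferon-stimulated genes and progenitors in lung against blood, and neutrophil identity, NADPH oxidase, heat shock, glycolysis, epithelium, endothelium, fibroblasts and stromal signals in lung against bone marrow. The stromal score ended erythroid genes in blood against bone marrow (0.0566), transcription factors, progenitors and ribosomal proteins in lung against blood, and neutrophil identity, NADPH oxidase, heat shock, glycolysis, stromal signals and ribosomal proteins in lung against bone marrow. Its other 3 losses, fibroblasts in blood against bone marrow and epithelium and fibroblasts in lung against bone marrow, come from lists that make up the score (with endothelium), and B cells under the B-cell score from the list that is that score, so these test nothing, and the gene count of the stromal score includes members of its lists. Limma-voom ended primary granules, B cells, erythroid and fibroblast genes in blood against bone marrow, tertiary granules, transcription factors, apoptosis and progenitors in lung against blood, and erythroid genes and stromal signals in lung against bone marrow. The B-cell score otherwise ended fibroblasts in blood against bone marrow, tertiary granules and transcription factors in lung against blood and stromal signals in lung against bone marrow, and DESeq2 the transcription factors and the stromal signals. Limma on the deposited FPKM ended 1 gene and 18 list calls and gave 7 and 2 new ones, over the 114 gene and 78 list results it had. FPKM gave no value for 51 gene and 21 list results. The filter of 50 counts gave none for 5 and 6, and the 6-library fit none for 2 lists. RSEM counts reach only lung against blood.

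The NF-kB response list in lung against blood kept its camera call under every scaling, filter, tool, covariate and left-out library, with medians of 1.43 to 2.03, and lost it with an estimated correlation. Depth limits genes under about 0.0714 CPM. The self-test recovered few small folds, with fewer changed genes than were called in these data.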

Other observations

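All tests in this part were chosen after the results they bear on had been seen.

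Libraries were also regrouped at random. For blood against bone marrow, lung against blood and lung against bone marrow, the 10 splits of 6 libraries are too few for a share under 0.05: the real splits gave 2892, 3900 and 5158 genes by edgeR and the highest other 1, 0 and 0. The 3 other splits that part every replicate number gave 0 genes in each. Of the 100 drawn from 280 groupings of the 9 libraries, only the real one gave 6223 genes that differ among tissues (highest other 2406), 1039 highest in lung (589) and 1256 highest in bone marrow (553).

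The replicate numbers pair the samples only as a hint from the data, clearest for replicate 3, since the labels name no shared animal or day. All 36 groupings that part every number were also fitted. Only the real one gave as many genes that differ among tissues (highest other 1627, or 661 against 7286 with the block). Over the 108 groups of these groupings, 2 held as many highest genes as lung and 1 as many as bone marrow, with and without the block, and no group outside the real grouping held over 589. In both sets no other grouping reached these 3 counts, a share under 0.05. The second set rests on the hinted pairing.

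For the 386 genes highest in blood by edgeR the sets differ. Of the drawn groupings 5 of 100 gave as many (highest other 820), a share not under 0.05. All 4 others had drawn the whole lung or bone marrow under the name of blood. With every number parted, the group of blood replicate 1 was called blood, so that no other whole tissue can bear the name. Then 1 of 36 groupings gave as many (highest other 0), the real one, a share under 0.05. Over all 108 groups of these groupings 9 did, each a whole tissue. Whether the share lies under 0.05 thus rests on whether whole tissues under another name are counted. With the block, 1 of 36 groupings reached 620 (highest other 0), and 3 of 108 groups, each a tissue of the real grouping. Both shares for the blocked count lie under 0.05, within the hinted pairing.

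Of the 1780 genes that rose in lung against blood, 728 lay below a log2 ratio of -1 between lung replicates 3 and 1.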
